A study of Caenorhabditis elegans with 2 samples.

How the data were processed

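NHR-76 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L1 larvae of Caenorhabditis elegans. The series holds 2 libraries, biological replicates 1 and 2 per the labels, from separate biosamples. The labels do not say whether these came from separate cultures, so any spread between them may be partly technical. They form 1 group, and no second group was analysed here.

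The deposited files are lists of genomic regions in the narrowPeak format. Per the library listings deposited with them, each library's list was derived from its alignments and a control file, the pooled list from the reads of both libraries, and the thresholded list from the pooled list and both library lists. The listings name the irreproducible discovery rate (IDR) as the step behind the thresholded list. The peak caller, the IDR threshold, the aligner and the number of reads per library were not given in the sources used here, and the control file was not used here. Every list was deposited on the builds ce11 and ce10. The deposited signal of a region is the caller's own value, the authors' and not scaled to a common depth as far as stated; it was used to rank and describe regions. The second value used is the deposited −log10 of a q-value, so named by the column order of the format.

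Each ce11 list of a library, and the pooled list, held 30000 regions. The region width was 344 bp for replicate 1, 310 bp for replicate 2 and 324 bp for the pooled reads. In replicate 1, 794 regions had a q-value at or below 0.05, in replicate 2 2004 and in the pooled list 695. The thresholded list held 248 peaks on ce11. These 248 were exactly the 248 strongest regions of the pooled list, with 0 mismatches, so pooled rank alone separates them from the other pooled regions. How the IDR step set their number was not given. A peak need not be among the strongest regions of each library. The reads behind each region are unknown, and intervals given for shares of peaks are 95% Wilson intervals that cover counting error only.

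Coordinates are on ce11, which is the same assembly as WBcel235, and are 1-based. Genes came from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. The summit is the position the file gives, which is the middle of every region. A peak gene is a protein-coding gene whose 5' end lies within 1 kb of a peak summit. The ce10 lists were compared with the ce11 lists by number, signal and rank, without converting coordinates; a counterpart had a signal within 0.1% and a summit within 20000 bp on the same chromosome.

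The 29716 pooled regions that overlap no peak served as background. Shares of peaks by location and by gene class were tested against 1000 random placements on the same chromosomes with two-sided permutation tests, and against the background with Fisher's exact test. The overlap of the libraries was tested with 1000 random placements (one-sided permutation test, overlap of at least 1 bp). Signals were correlated across peaks with 100000 permutations. Chromosome shares were tested with exact binomial tests. The 16 gene lists, fixed before the data were examined, were tested with Fisher's exact test against the 10328 genes near any region of the pooled list. The 9 fixed motifs, and separately all 2080 6-mers, were sought within 75 bp of summits and in as many background regions matched on GC and on X or autosome. P-values were adjusted by the Benjamini-Hochberg method within each family. The number of peaks within 25 kb of the middle of nhr-76 was set against 10000 random windows of 50 kb. That the window was centred on the middle of the gene was settled after peak positions had been seen.

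The genes named were set by a rule fixed before the data were examined. It takes the protein-coding genes within 1 kb of the 20 strongest summits (the nearest one where none is that close), nhr-76, up to 4 members of each list with the strongest peaks, and every member of the fat-loss list with a peak. A signal is given for each named peak as the pooled value in the caller's units, or as the mean ± SD of the 2 libraries after dividing each by the median listed region of that library.

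Alternatives were the 124 strongest peaks, each library's own 248 strongest regions, other distances, windows and overlaps, the nearest gene alone, other backgrounds and the ce10 lists. Alternatives added after the data had been seen were merged overlapping peaks for the gene lists and RNA gene classes (planned for the peak count), the 248 pooled regions next in rank, a gene background near 10 GC-matched regions per peak, the correlation over all pooled regions, X and autosomal peaks apart for distance to 5' ends, and a window centred on the 5' end of nhr-76. The settings for snoRNA and snRNA genes were also added then.

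The tests were tried on simulated data. In lists planted at an odds ratio of 3, the lipid metabolism list was called in 5 of 100 simulations and the nuclear receptor list in 30 of 100. At an odds ratio of 6 these numbers were 38 and 97. The fat-loss list was not simulated. At an odds ratio of 12 these numbers were 92 and 100. The motif TGATAA, planted in an added 20% of windows, was called in 18 of 20 simulations, and in an added 10% in 3 of 20. Those windows were drawn at random from listed regions outside the peaks, which averaged 37.97% GC against 47.7% in peaks. No other motif was planted, so the power at peaks and for other motifs may differ. Scripts ran under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and sequences were compared with blastn 2.17.0.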

Results

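NHR-76 belongs to the nuclear hormone receptors, a large family of transcription factors in nematodes, and is known for a role in serotonin-driven fat loss in the intestine. Its binding was profiled by ChIP-seq in whole L1 larvae, the stage after hatching, of strain OP203, which expresses the receptor with a GFP-FLAG tag at its C-terminus. The data comprise 2 libraries of 1 group, so the questions they address are where in the genome the receptor's signal lay and how alike the libraries were. The deposited result is a list of 248 peaks on the ce11 build, each 324 bp wide, with pooled signals from 30.8 to 114.6 and a median of 39.3 in the caller's units. The number of reads per library is unknown, and no control ChIP without the tagged receptor was analysed here. Signals given below as multiples are each library's value divided by its median listed region, as mean ± SD (n = 2 libraries).

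Of the 20 strongest peaks, 9 had a protein-coding 5' end within 1 kb and 11 did not. The strongest of all (III 1618989 to 1619312, pooled signal 114.6, 8.67 ± 0.829 times the median region) was intergenic, 591 bp upstream of hsp-60 (WBGene00002025), which encodes the mitochondrial chaperonin, and 222 bp upstream of the divergent gene Y22D7AL.10. The next (I 4172007 to 4172330, 7.31 ± 0.0318 times) overlapped sls-2.4, a gene for an SL2 spliced leader RNA, 580 bp upstream of egg-5. The peak at V 10897223 to 10897546 lay 242 bp upstream of sec-61.G, a subunit of the protein translocation channel of the endoplasmic reticulum, and 842 bp upstream of F32D8.13; its libraries averaged 6.88 ± 2.39 times. The peaks ranked 3 and 5 (X 9465692 to 9466015, 7.54 ± 0.294 times, and X 13700705 to 13701028, 7.04 ± 0.974 times) were intergenic, 2509 bp from the 5' end of ZK899.6 and 6040 bp from that of K02D3.1. The rpl-3 peak (III 3867416 to 3867739, 276 bp upstream) averaged 6.88 ± 4.67 times, with 3.57 in replicate 1 and 10.2 in replicate 2, so its height rested largely on replicate 2. A peak at I 1835428 to 1835751 (6.51 ± 1.15 times) lay between rpl-27 and egl-30, a Gq alpha subunit, with its summit 71 bp upstream of egl-30 and 190 bp upstream of C53H9.4.

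Other peaks among the 20 strongest lay 48 bp upstream of tasp-1 (6.60 ± 1.06 times; K01G5.10 lay within 1 kb as well), 299 bp upstream of serp-1.1 (6.01 ± 2.14 times), 79 bp upstream of the histone gene his-37 (5.33 ± 0.722 times, also near C50F4.6) and 383 bp upstream of rpl-15 (6.01 ± 3.04 times, also near K11H12.8). The genes nearest to the 11 peaks without a 5' end within 1 kb were ZK899.6, K02D3.1, ins-13, mom-1, W02H3.3, F20B6.9, pxn-1, T27A8.7, C41A3.2, drap-1 and F55G7.5. The ins-13 one overlapped a second SL2 RNA gene, sls-2.2, and the pxn-1 one overlapped the snoRNA gene ZK994.7 inside an intron.

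Among the 16 gene lists, cytosolic ribosomal proteins and heat-shock and chaperone genes were enriched among the 205 genes with a peak within 1 kb. Ribosomal protein genes made up 12 of them where 1.53 were expected from the 77 list members in the background (odds ratio 9.61, 95% interval 4.65 to 18.3, Fisher's exact test, adjusted p = 5.14e-07). The strongest were rpl-3, rpl-27, rpl-15 and rpl-35 (4.70 ± 1.87 times at rpl-35). Of the 12 summits, 9 lay upstream of the gene, and the others, that of rpl-27 among them, lay past its 3' end. Chaperone genes made up 7 where 0.655 were expected from 33 (odds ratio 13.7, 4.97 to 32.9, Fisher's exact test, adjusted p = 2.42e-05). Their strongest were hsp-60, hsp-90 (the cytosolic HSP90, 4.40 ± 0.0393 times, summit 863 bp downstream of the 5' end, in an intron), hsp-3 (a BiP of the endoplasmic reticulum, 4.30 ± 3.01 times) and dnj-13 (a DnaJ co-chaperone, 3.04 ± 0.308 times). The peak counted for another member, hsp-12.3, named after its values were seen, overlapped the snRNA gene F38E11.11 and had 1.04 times the median region in replicate 1. Both calls held with either library left out, but their sizes moved: the ribosomal odds ratio was 6.36 (9 members) without replicate 1 and 13.6 (14 members) without replicate 2, and the chaperone odds ratio was 10.6 (6 members) without replicate 1 and 7.97 (4 members, Fisher's exact test, adjusted p = 0.0129) without replicate 2. Peaks were richer in GC than the other listed regions, with a mean of 47.7% against 37.97%. Against genes near GC-matched regions, an alternative chosen after the data had been seen, the ribosomal list was no longer called. It had 12 of 46 members (odds ratio 2.12, 0.983 to 4.29, Fisher's exact test, adjusted p = 0.161). The chaperone list was still called (7 of 9, odds ratio 21.03, Fisher's exact test, adjusted p = 0.000399). This background of 1401 genes held 46 of the 77 ribosomal members, so it cannot separate GC from the kind of gene compared. With the nearest gene alone, the ribosomal list was called (8 members, odds ratio 8.49, Fisher's exact test, adjusted p = 0.000194). The chaperone list was not called in that setting (odds ratio 7.10, Fisher's exact test, adjusted p = 0.0886). Without a control ChIP, neither call can tell binding of the receptor from a general pull-down of highly transcribed, open sites.

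**Figure D1:**
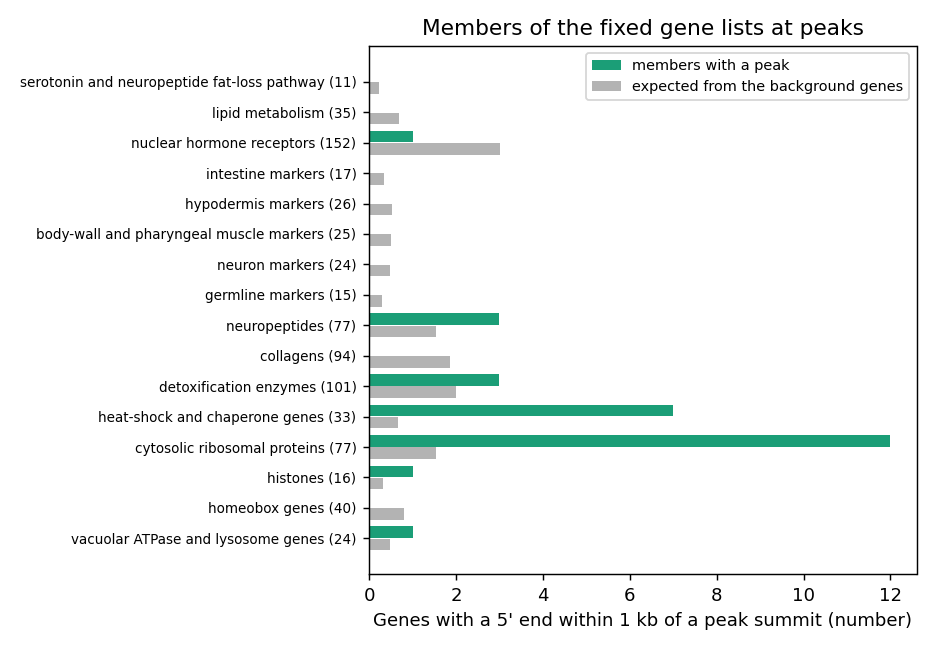
Number of genes of each list with a 5' end within 1 kb of a peak summit (green) and the number expected from the background genes (grey); the number after each list name is its members in the background. Ribosomal proteins (12 against 1.53) and chaperones (7 against 0.655) stand above the expected numbers.

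No member of the fat-loss list (11 in the background) or the lipid metabolism list (35) had a peak within 1 kb; the number of members with a peak was 0 in each, and the expected numbers were 0.218 and 0.695. Likewise 0 members had a peak among markers of the intestine (17), hypodermis (26), muscle (25), neurons (24) and germline (15), collagens (94) and homeobox genes (40). Expected numbers in these lists were at most 1.87, so a depletion could not have been detected. The upper bound of the odds ratio was 5.52 for lipid metabolism and 19.8 for the fat-loss list. Nuclear hormone receptors had 1 member with a peak, nhr-255 (odds ratio 0.324, Fisher's exact test, adjusted p = 0.874), and that peak overlapped a tRNA gene. Neuropeptides had 3 (nlp-4, ins-39 and ins-13; odds ratio 2.02, Fisher's exact test, adjusted p = 0.874), detoxification enzymes had 3 (ugt-11, ugt-9 and gst-27; odds ratio 1.52, adjusted p = 0.911), and histones (his-37) and vacuolar ATPase and lysosome genes (vha-8) had 1 each (both adjusted p = 0.874). The histone list, not called in the peaks, was called with 3 members in the strongest regions of either library alone. It passed without replicate 1 (odds ratio 10.8, Fisher's exact test, adjusted p = 0.0226) and without replicate 2 (odds ratio 13.3, Fisher's exact test, adjusted p = 0.0129). The peaks near nlp-4 and gst-27 overlapped snoRNA genes, and the ins-13 peak overlapped the SL2 RNA gene sls-2.3.

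Peaks on the autosomes lay close to gene starts, and for X this was not shown. Of the 248 summits, 149 (60.1%, 53.9 to 65.98) were within 1 kb of a protein-coding 5' end, against 34.1% on average after random placement. The permutation p was 0.002, the smallest that 1000 placements can give in a two-sided test. Among the other listed regions the share was 38.2% (odds ratio 2.43, 1.87 to 3.17, Fisher's exact test, p = 4.51e-12). On the autosomes 129 of 194 summits were this close (66.5% against 35.7% at random, permutation p = 0.002, again the smallest possible). On X it was 20 of 54 (37.0% against 28.8% at random, permutation p = 0.236), a split by chromosome chosen after the data had been seen. Intergenic sequence held 144 summits (58.1%, against 34.6% at random), exons of non-coding genes 43 (17.3% against 2.996%) and 5' UTRs 11 (4.44% against 1.42%). Coding exons held 9 (3.63% against 24.5%), introns of protein-coding genes 40 (16.1% against 33.1%) and 3' UTRs 1 (0.403% against 3.40%). After adjustment over these 6 classes the permutation p was 0.004 for 3' UTRs and 0.0024 for each other class, adjusted from the smallest that the placements can give.

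Short non-coding RNA genes were a frequent location. At least 1 tRNA, snoRNA or snRNA gene was overlapped by 50 of the 248 peaks (20.2%, 15.6 to 25.6), against 0.458% on average and 2.02% at most after random placement and 1.28% of the other listed regions. Among 5 listed regions per peak matched on GC, compared after the peaks had been seen, the share was 9.19% (7.71 to 10.9). tRNA genes were under 20 peaks (8.06%, random average 0.263%), snoRNA genes under 19 (7.66%, 0.149%) and snRNA genes, a class that here includes the SL2 RNA genes, under 11 (4.44%, 0.0472%). For each of the 3 classes the permutation p adjusted over 4 classes was 0.00266, from the smallest that the placements can give. miRNA genes were under 1 peak (adjusted permutation p = 0.458). Some rows overlap each other: with the strongest of each such group kept, 48 of 244 peaks lay at tRNA, snoRNA or snRNA genes (19.7%, 15.2 to 25.1), 9 of them at snRNA genes, and 0 at miRNA genes. The tRNA share was 4.84% among the strongest regions of replicate 2 alone and 6.85% in replicate 1 alone, so leaving out replicate 1 lowered it most. Of the 50 peaks, 26 hold a stretch of at least 50 bp with a second genomic match at 95% identity, so reads could be split or misplaced there.

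The X chromosome held 54 peaks (21.8%, 17.1 to 27.3), against its 17.7% of the genome, a difference that did not pass the threshold (exact binomial test, p = 0.0957, adjusted over 6 chromosomes p = 0.191). Peaks per Mb ranged from 1.82 on V to 3.48 on III, where 48 peaks lay (exact binomial test, adjusted p = 0.0763), and no chromosome passed after adjustment. Position by strength was uneven: 9 of the 20 strongest peaks were on X (45%, 25.8 to 65.8, exact binomial p = 0.00429, a number of peaks chosen after their positions had been seen). Among the 124 strongest the share was 28.2% (exact binomial p = 0.00433), and among the strongest regions of each library alone it was 22.6% in replicate 1 (p = 0.0457) and 21.4% in replicate 2 (p = 0.134). Against X's share of the other listed regions, 18.9%, the exact binomial p for all peaks was 0.256. X-linked peaks were also more often far from gene 5' ends, though some of these lay inside genes. Over 1 kb from a protein-coding 5' end were 34 of 54 (63.0%), against 65 of 194 (33.5%) on autosomes (odds ratio 3.36, 1.72 to 6.68, Fisher's exact test, p = 0.000139). Listed X-linked regions outside the peaks were far from 5' ends in 69.0% of cases (odds ratio 0.762, 0.425 to 1.40, Fisher's exact test, p = 0.375). The central part of the chromosomes, 33.3% of their length, held 92 peaks (37.1%, exact binomial p = 0.225).

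**Figure D2:**
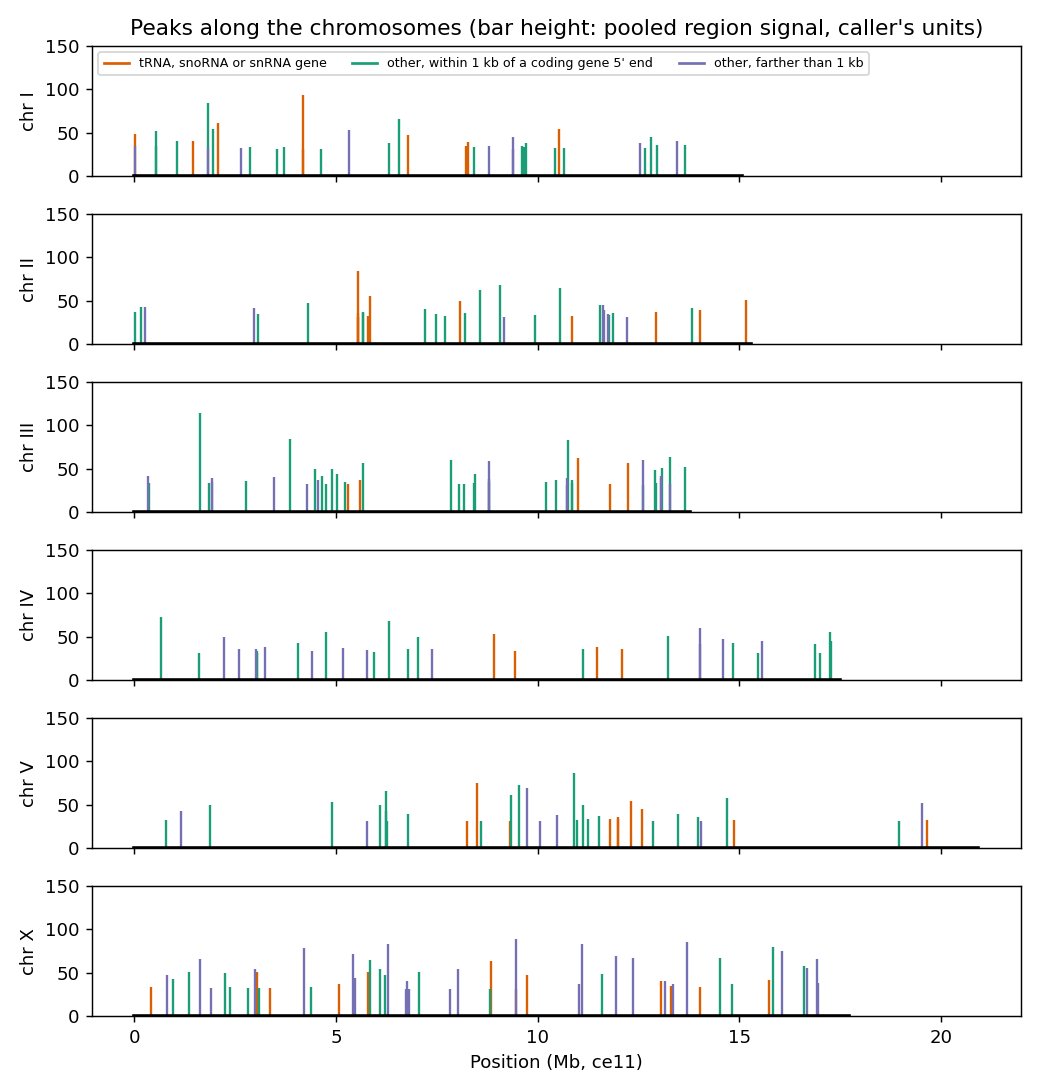
The 248 peaks along the 6 chromosomes (position in Mb, ce11); bar height is the pooled signal in the caller's units, and colour marks peaks at a tRNA, snoRNA or snRNA gene (orange), other peaks within 1 kb of a protein-coding 5' end (green) and peaks farther away (purple). On X, 34 of 54 peaks lie over 1 kb from a 5' end, and 8 of these are among the 20 strongest of all.

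The libraries shared part of their strongest regions. Of the 248 strongest regions of replicate 1, 100 (40.3%, 34.4 to 46.5) overlapped one of the 248 strongest of replicate 2, against a mean of 0.167% and a maximum of 1.61% after random placement (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). Of the 248 peaks, 97 were among the 248 strongest regions of both libraries, 64 of replicate 1 alone, 64 of replicate 2 alone and 23 of neither. Within the 1000 strongest regions, 188 were in both and 0 in neither. Across the 244 peaks matched in both lists, which are not independent replicates, Spearman's rho was 0.142 (permutation p = 0.0258) and Pearson's r of log2 signals 0.14 (permutation p = 0.0330). Peaks that overlap each other could be matched to the same library region. Some values therefore enter these counts and correlations more than once, and merged peaks were not tried for them. Without the 2 peaks farthest from the median of replicate 1, r was 0.13 (permutation p = 0.0499). Among the 124 strongest peaks rho was 0.0928 (permutation p = 0.306), and on ce10 0.108 (permutation p = 0.103). The peaks are the strongest regions by the pooled signal of the same libraries, a selection that narrows the range and lowers a correlation between them, so these values do not measure how alike the libraries ranked regions. Over the 8508 pooled regions matched in both lists, a set chosen after the data had been seen, r was 0.35 and rho 0.174 (both permutation p = 0.000999, the smallest that 1000 permutations can give). That set is itself selected, as it leaves out the pooled regions not listed in both libraries, and rho rose less than r.

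**Figure D3:**
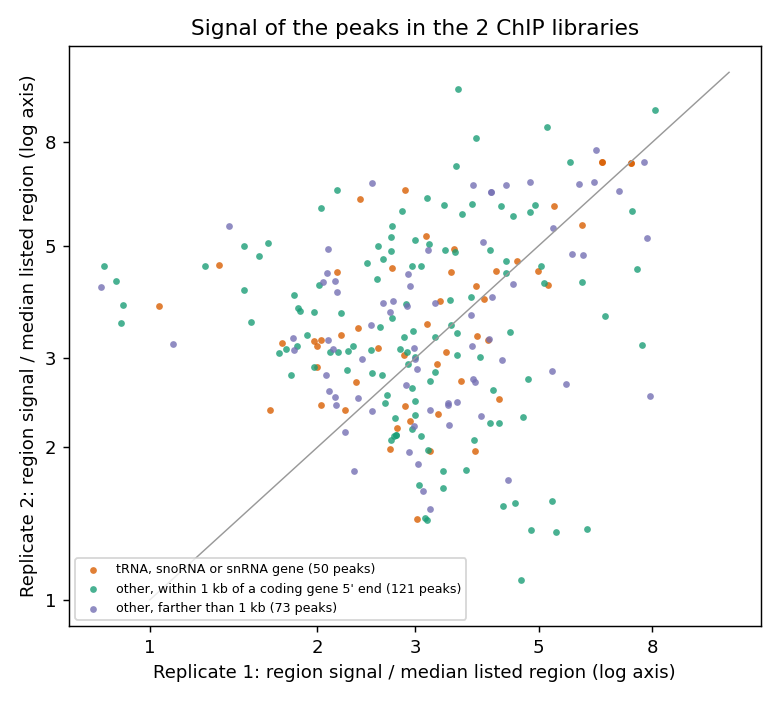
Signal of the peaks in replicate 1 (x axis) and replicate 2 (y axis), each divided by the library's median listed region, on log axes; each point is 1 of the 244 peaks matched in both, coloured by gene class, and the line marks equal values. Spearman's rho over these peaks, which were selected on pooled signal, is 0.142, with the hsp-60 peak at 8.08 and 9.25.

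On ce10 the list held 229 peaks. Of the 248 ce11 peaks, 228 had a ce10 counterpart, and the 20 without one ranked between 173 and 248. Overlapping rows left 244 distinct peaks on ce11.

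The nhr-76 gene itself (WBGene00015497, IV 627537 to 633963, plus strand) had no peak at it. The window of 25 kb to either side of its middle held 1 peak, the rpl-15 one near the window's edge, against 0.123 on average (permutation p = 0.108), and the window of 10 kb held 0. The strongest pooled region at the gene or 1 kb upstream (IV 631840 to 632163, signal 18.8) ranked 1406. The window was dense in listed regions below the peak threshold: 29 pooled regions, where 95% of random windows held 6 to 25.

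None of the 9 fixed motifs was enriched at summits, that is 0 by Fisher's exact test with adjustment, and 0 at an unadjusted p under 0.05. The nuclear receptor half-site AGGTCA was within 75 bp of 13 summits (5.24%) and of 13 matched regions (odds ratio 1, 0.417 to 2.40), and AGTTCA of 8 against 13 (odds ratio 0.603, 0.213 to 1.60). The GATA site TGATAA was at 21 against 16 (odds ratio 1.34, 0.648 to 2.82) and the GC box GGGCGG at 37 against 25 (odds ratio 1.56, 0.882 to 2.81, Fisher's exact test, p = 0.135). Of 2080 6-mers, 0 passed after adjustment and 97 had an unadjusted p under 0.05, no larger a share than that threshold allows where no 6-mer differs. Without matching on GC, GAGAGA and GGGCGG were called, with adjusted p of 5.71e-10 and 6.63e-07.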

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

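The counts in this part were chosen after the peaks had been seen. Outside the 248 peaks, 440 listed pooled regions had a q-value at or below 0.05, and 69 of them were overlapped in both libraries by a region with such a q-value. They stand out because the thresholded list leaves them out. No comparison above uses them as a set, though some can be among each library's own 248 strongest regions or the 248 next in rank. Cytosolic ribosomal protein genes, 12 of which had a peak, had 11 further members within 1 kb of the 440 regions, 23 in all; no test of this count was run. Among the 248 regions next in rank after the peaks, 5 members were found and the list was not called (odds ratio 3.93, Fisher's exact test, adjusted p = 0.187).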

How the results depend on the processing

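Chosen after the data had been seen were the settings for merged peaks in the gene lists and RNA gene classes, the next 248 regions, GC-matched gene backgrounds, all pooled regions, X and autosomes apart, the 5'-end window at nhr-76 and the snoRNA and snRNA genes. The shares of summits near 5' ends, of peaks at tRNA, snoRNA and snRNA genes, and of regions shared by the libraries kept their direction and side of the threshold in the settings run on all chromosomes together. X-linked peaks taken alone did not pass for 5' ends (37.0%, permutation p = 0.236). The middle of the peak equals the summit and tests nothing. The number of enriched gene lists, 2, was 1 with the nearest gene alone, 1 with GC-matched backgrounds and 0 in the next 248 regions. Leaving out either library gave 3 lists, with odds ratios of 6.36 and 13.6 for ribosomal proteins and 10.6 and 7.97 for chaperones, histones being added (adjusted p 0.0226 and 0.0129). The number of motifs, 0, was 2 without GC matching, where peaks had 47.7% GC against 37.97%, and matching removed both. GAGAGA was at 31.9% of peaks, 8.47% of unmatched and 32.7% of matched regions. Matching may also change the kind of region compared, so GC itself was not shown to be the cause. The peak count near nhr-76, 1, was 0 within 10 kb and 0 in the window centred on the 5' end, as both leave out the rpl-15 peak. The rank correlation of the libraries, 0.142, was 0.189 (permutation p = 0.00535) with summits matched within 100 bp, 0.0928 in the 124 strongest peaks and 0.108 on ce10, these last 2 no longer past the threshold, and 0.174 over the 8508 pooled regions matched in both, where Pearson's r was 0.35 against 0.14 in the peaks; choosing peaks by pooled signal lowers such correlations by construction, and other causes were not tested. The X share, 21.8%, passed the threshold at 28.2% in the 124 strongest peaks and at 23.4% in the next 248 regions, and ranged from 21.4% to 22.6% when either library was left out, passing without replicate 2; the cause was not tested. No paired analysis was possible because there is 1 group. Reads per region are unknown, which limits how far weak regions can be ranked.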

Other observations

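The tests of explanations in this part were set out before their results were seen, but all except the one on nhr-76 after the peaks themselves had been looked at; the grouping by SL RNA, RNase P and X-linked tRNA genes was chosen after values were seen. SL2 RNA genes, whose product is joined to messages from downstream genes of operons, were under 7 peaks, or 5 once overlapping rows were merged, which covered 5 of 18 genes (sls-2.1, sls-2.2, sls-2.3, sls-2.4 and sls-2.8). SL1 RNA genes were under 0 peaks, with 0 of 12 under any listed pooled region, so nothing can be said of this family from these lists. The genes for the RNase P RNA (rpr-1) and the RNase MRP RNA (mrpr-1), both 2 of 2, were each under a peak. Of the 20 peaks at tRNA genes, 12 were on X (60%, 38.7 to 78.1), which holds 45.1% of the 612 tRNA genes.

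Peaks at tRNA, snoRNA and snRNA genes could come from technical sources. A single library does not explain them, since the lower of the 2 libraries still had 16.5% of its strongest regions at such genes, against at most 2.42% after random placement. The tables argue against GC content as the whole cause: 9.19% (7.71 to 10.9) of GC-matched regions lay at these genes against 20.2% (15.6 to 25.6) of peaks, though the rise from 1.28% without matching leaves room for a part. Shared reads over stretches of at least 50 bp at 95% identity, taken alone, are not the whole cause either. The 24 peaks without such a second match made up 9.68% of all peaks, above the random maximum. Read length was not taken into account and the aligner was not given, so sharing over shorter or less alike stretches stays open. The 2% with a second match of 200 bp decides nothing, as all 52 genes are shorter than 200 bp. However, random placement takes no account of GC. The 9.68% cannot be set against the 9.19% of GC-matched regions either, as that share counts regions with and without a second match. GC content and shared reads acting together therefore stay open, as no test took both at once. Also open is a general pull-down of highly transcribed, open sites, which a control ChIP not used here would address. The same stays open for peaks near gene 5' ends, ribosomal protein genes and chaperone genes. No biological explanation was tested, since there is 1 group.

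X-linked peaks far from gene starts may include sites that recruit the dosage compensation complex, which is known to bind X at elements with a 12-bp motif; this reading is a hypothesis from background knowledge. The motif TCGCGCAGGGAG, with up to 2 mismatches within 150 bp of the summit, was in 11 of 34 such peaks (32.4%, 19.1 to 49.2). It was in 0.766% of other listed X-linked regions (odds ratio 61.5, Fisher's exact test, p = 5.07e-15) and in 2.06% of autosomal peaks. X-linked peaks within 1 kb of a 5' end had it in 2 of 20 cases (10%, 2.79 to 30.1), an interval that overlaps that of the far peaks. With up to 1 mismatch the odds ratio against other X-linked regions was 394.5, and with up to 3 it was 11.4. With up to 3 mismatches the odds ratio against autosomal peaks was 3.10. GC content did not account for the motif share, at 1.76% (1.01 to 3.06) of GC-matched X-linked regions, and the motif was in 11 of the 20 strongest X-linked peaks but in 1 of 58 X-linked regions among the next 248; exact copies lay at X 11094034 to 11094357 (intergenic) and X 2996945 to 2997268 (an intron). Another 9 of the 34 peaks overlapped a tRNA gene and 14 had neither, and the lower density of genes on X stays open for their distance, with an odds ratio of 0.762 against other X-linked regions. Whether NHR-76 itself or open chromatin at these sites gave the signal cannot be settled without a control ChIP.

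Extra copies of the tagged locus might raise the signal around nhr-76. The median pooled signal of listed regions in the 50 kb window was at percentile 93.6 of random windows, below the bound set beforehand, but that bound was no fair exclusion because the libraries lay on both sides of it, at 98.7 in replicate 1 and 80.8 in replicate 2. The number of listed regions, 29 pooled and 31 in replicate 1 against an upper random bound of 25, points the other way, while replicate 2 had 24. Extra copies and chance cannot be told apart here, as the libraries disagree and the copy number in the control is unknown.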
